A study of Arabidopsis thaliana with 4 samples.

How the data were processed

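Gene expression was measured on Affymetrix arrays of Arabidopsis thaliana, with 1 array for each of 4 conditions: R:FR of 4.4 or 0.1, at 16 or 22 °C. The deposited values are linear intensity values, 1 signal per probe set, made with MAS5 per the submitters' processing notes. The version, target and background settings of MAS5, and its detection calls, are not given in the sources used here. The signals of the table were never negative, and the mean without the highest and lowest 2% of values was about 100.01 on each array, so the deposited signals had been scaled as a whole array. The labels' protocols give RNA extraction with a column kit and phenol, and labelling by the array maker's protocol. Nothing names batches or scan dates, so those were not tested.

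From these values, each array was scaled to the same 2% trimmed mean, values below the 30th percentile of all scaled values (a signal of 14.5) were set to that floor, and log2 was taken. The 64 control probe sets were left out. Of the other 22746, the 13648 whose mean log2 over the 4 arrays was at or above the 40th percentile (a signal of 23.2) counted as measured. Bacterial control transcripts with no partner in the sample (27 probe sets, 108 values) had a median signal of 2.2, and 2 of the values lay above the floor. A fold against a value at the floor is given as a bound, "at least". The floor limits every fold of a dim gene. The lowest and highest signals of the 18 spiked probe sets were 34.5 and 3280, so neither dimmer nor brighter signals are covered by that scale of error. Genes with several measured probe sets (61 genes) had an SD of 0.49 between the log2 light responses of their probe sets at 16 °C and of 0.43 at 22 °C.

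Gene names came from a table of probe sets and genes, with symbols updated through the gene number to RefSeq's table. Of the 22746 probe sets 13513 had 1 gene, of which 13436 were matched, 503 had several genes and named none, and 8730 were unnamed here. A symbol is a gene name other than a locus tag. Of the measured probe sets 7320 had 1 gene and 1079 a symbol, so the named genes are a small part of the probe sets past each threshold, and coordinates are not printed because no genome build is stated for the values. Mitochondrion-encoded probe sets were recognised by their symbols and chloroplast-encoded ones by RefSeq's chromosome.

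With 1 array per group, the 5 comparisons (light at each temperature, their difference, and temperature in each light) are counts of measured probe sets at least 2-fold higher or lower, a rule of size and not a test. The local SD beside a gene is the median absolute deviation, scaled to equal the SD of a normal distribution, of the log2 changes of the 500 probe sets nearest in mean signal. A list's median is given as its percentile among 10000 random lists of the same size, drawn with replacement from measured probe sets with 1 gene in 20 bins of mean signal. This describes these arrays and tests nothing, and 30 such percentiles were computed for lists fixed beforehand. The only test was limma on all 4 arrays, with lmFit on a term for light and a term for temperature, eBayes with a trend, and Benjamini-Hochberg adjustment, which leaves 1 residual degree of freedom, the interaction. Its p-values set each effect against the departure from additivity between these arrays, which serves as its error, and nothing says how many plants or cultures each array holds.

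The groups, the comparisons, the alternatives, 24 gene lists of 277 genes and the rule for naming genes were fixed before the data were examined. The rule named the 10 highest and 10 lowest changes of each light comparison, the 8 highest and lowest differences, and the 6 highest and lowest of each temperature comparison, among measured probe sets with 1 gene and a symbol whose brightest value in the comparison reached the median of all signals (37.8). It also named list members past 2-fold or otherwise the 2 nearest the list median, the 10 smallest adjusted p-values of each effect, PHYA and the reference genes. Of the listed genes 41 had a named probe set and 32 were measured. Measured were 6 of 21 genes of the cold-regulated list, 3 of 15 of the auxin list and 4 of 13 of the cell wall list. For the light-harvesting list it was 3 of 15, for the flavonoid list 3 of 17 and for the reference list 3 of 10. Lists with at least 3 measured genes (6 of them) were given a median, and 9 lists had no measured gene: ethylene, heat shock, abscisic acid, light signalling, the mutated gene, flowering, starch and sugar, seed markers and apex markers. The organelle-encoded groups and the gene families of the closing part were chosen after the values were seen. Each listed gene had 1 probe set, so the planned mean over the probe sets of a gene changed nothing.

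Alternatives were the values as deposited, scaling to the same median, quantile normalization, a floor at the 10th or 50th percentile, a pseudocount equal to the floor in its place, no filter, a filter at the 60th percentile, a 3-fold rule, eBayes without a trend and a fit without the other factor. Floor alternatives kept the main measured set. The scripts were tested on simulated data in which 200 of 13648 probe sets were changed. The simulated noise was normal, with an SD for each bin of mean signal taken from the departure from additivity, and no floor was applied. The rates below therefore need not hold for the real arrays. For the comparison of light at 16 °C, the 2-fold rule recovered 46% of 50 probe sets changed by log2 1 and 100% of those changed by 2, 3 or 4, and 106 of 13448 unchanged ones passed it. For the light effect over both temperatures, limma recovered 60% of 25 probe sets changed by log2 1 at both temperatures, 76% at log2 2, 100% at 3 and 96% at 4, 0% of those changed at 16 °C alone, and called 0 unchanged ones. Of 100 unshifted random lists of 15 probe sets, 87 lay between percentiles 5 and 95. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.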

Results

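Transcript levels were measured in seedlings of Arabidopsis thaliana at 2 temperatures and under 2 light qualities, with 1 array of 22810 probe sets for each of the 4 conditions. All plants came from the accession La-er and carried phyA-2, a mutation in PHYA, the gene of the far-red photoreceptor phytochrome A. They were grown on soil in white light of 100 micromoles per square metre per second with a ratio of red to far-red light (R:FR) of 4.4, at 16 or at 22 °C. Plants of the low R:FR groups received an R:FR of 0.1, a signal of neighbouring vegetation, for the last 24 h, and all plants were 5 days old at harvest. RNA came from cotyledons with a little hypocotyl. The deposited signals had the same trimmed mean on every array, about 100.01, and medians between 36 and 40.6. Pearson's r of log2 signals over the 13648 measured probe sets was lowest between the low R:FR arrays of 16 and 22 °C, at 0.93, and highest between the arrays of high and low R:FR at 22 °C, at 0.975. No condition was repeated, so the comparisons of single arrays have no replicate check and no p-value, and the number of arrays limits the precision. As a scale of error from hybridization onwards, 18 probe sets of transcripts spiked in at hybridization, with signals of 34.5 to 3280, had log2 differences with an SD of 0.21 between the light conditions at 16 °C and 0.23 at 22 °C. They do not cover variation between plants, RNA extractions or labelling reactions. A local SD, taken over the 500 probe sets nearest in mean signal, stands beside single genes below. Of the measured probe sets, 1079 had 1 gene with a symbol here. PHYA had no named probe set among them, and its level was not analysed.

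The first comparison asked which transcripts differed after 24 h of low R:FR at the lower temperature. At 16 °C, COR15A, which encodes a chloroplast protein known to protect membranes during freezing, was among the named genes with the highest changes. Its signal was 15.3 in high R:FR and 314 in low R:FR (log2 4.36, local SD 0.47). The lower signal is close to the floor of 14.5 and below 17.9, the highest signal of control transcripts absent from the sample, so the size of the ratio, 20.5, is uncertain, and it was 8.31 with a floor at the 50th percentile of signals. Its neighbour and paralog COR15B went from 55.2 to 588, 10.6-fold with either floor (log2 3.41, local SD 0.37). These 2 genes are similar in sequence, and cross-hybridization between their probe sets was not excluded. The dehydrin gene LTI30 had signals of 41.2 and 85.4 (log2 1.05). The list of CBF factors and cold-regulated genes had 6 measured genes of 21 listed. CBF1, CBF2 and CBF3 had no named probe set, so no CBF factor was measured. Of the 6 genes, 3 were at least 2-fold higher, 0 lower, and the median log2 of 0.94 lay at percentile 100 of 10000 random lists matched on signal. The other measured genes of that list were COR47 at log2 0.82, COR27 at 0.33 and AT4G33980 (COR28) at -0.50.

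Early auxin response genes were also higher in low R:FR at 16 °C. All 3 measured genes of that list passed 2-fold, with a median log2 of 1.33 at percentile 99.96. IAA29, a transcriptional repressor of auxin signalling, went from 28.5 to 180 (log2 2.66), WES1 (GH3.5) from 58.3 to 147 (log2 1.33) and GH3.3 from 49.5 to 99.2 (log2 1.003). GH3.3 did not pass 2-fold with a pseudocount in place of the floor. WES1 and GH3.3 encode enzymes that conjugate auxin to amino acids. None of the 4 cell wall genes passed 2-fold, but all 4 were above 0, with a median log2 of 0.55 at percentile 99.7, led by the expansin gene EXPA8 at 0.75 and XTH33 at 0.69. The 3 flavonoid genes were below 0, with a median of -0.71 at percentile 1.83, or -0.32 with a floor at the 50th percentile. Of these AT4G14090 (UGT75C1), an anthocyanin glucosyltransferase gene, passed 2-fold with signals of 47.2 and 20.2, but not with a floor at the 50th percentile. UF3GT was at log2 -0.71 and DFR at -0.63. The 3 light-harvesting genes had a median of -0.43 at percentile 0.59, with LHCB4.2 at -0.48, LHCB4.3 at -0.43 and LHCB4.1 at -0.04. The 3 reference genes had a median of -0.25 at percentile 11.2, with PEX4 (UBC21) at 0.04, AT2G28390 at -0.25 and AT4G34270 at -0.35.

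The lowest named changes at 16 °C included those of Prx37 and PUB23. Prx37, a peroxidase gene, had a signal of 93.2 in high and 15.9 in low R:FR (log2 -2.55, local SD 0.42, or -1.30 with a floor at the 50th percentile), the latter signal below the highest of the absent controls. PUB23, which encodes a ubiquitin ligase, had signals of 112 and 19.9 (log2 -2.49, local SD 0.32, or -1.56 with that floor). STZ (ZAT10), a zinc finger repressor of the early cold response and the only measured gene of its list, was 4.37-fold lower, with signals of 278 and 63.5. Other lower genes were SBT3.5 (log2 -1.98), which encodes a subtilase, and MSRB9 (log2 -1.88), which encodes a methionine sulfoxide reductase. For 5 genes the low R:FR signal lay at the floor, which leaves a bound. PDF1.2b, a plant defensin gene, was at least 4.95-fold lower, UGT76B1, a glucosyltransferase gene, at least 4.38-fold, ZCF37 at least 3.68-fold, the osmotin-like gene OSM34 at least 3.6-fold and CW14 at least 3.27-fold. None of these 5 passed 2-fold with a floor at the 50th percentile. The probe set of PDF1.2b is one that its array design marks as shared with other sequences.

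Chloroplast-encoded transcripts filled the other 8 places among the 10 highest named genes at 16 °C. They were ycf3 (signals 33 and 473), ndhE (log2 3.72), ndhG (24.2 and 298), rps14 (21.2 and 224), petN (19.6 and 187), petD (17 and 154), psbT (20.3 and 162) and rpoB (23.2 and 183). For ndhE and petD the lower signal was below the highest of the absent controls, and with a floor at the 50th percentile their log2 changes were 2.60 and 2.03. Over all 68 measured chloroplast-encoded probe sets, a group chosen after the values were seen, 19 were at least 2-fold higher, 0 lower, and the median log2 was 0.39. Their signal was lowest of the 4 arrays on the high R:FR array of 16 °C for 53 of the 68. That array was also the lowest for 6 of 7 mitochondrion-encoded probe sets.

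In total 251 measured probe sets were at least 2-fold higher and 395 at least 2-fold lower in low R:FR at 16 °C. Of these, 35 and 30 had a symbol, so the named genes above need not be the most changed ones. Without the demand for a symbol, 6 of the 10 highest and 1 of the 10 lowest changes had one. On the low R:FR array of 16 °C, 258 probe sets lay at least 2-fold below all 3 other arrays, against 70 on the high R:FR array of 16 °C and at most 17 on the others. The ratio of 3' to 5' signal of 6 pairs of probe sets for control transcripts, a measure of RNA and label quality, had a mean log2 of 0.54 on the low R:FR array of 16 °C and of 0.82 on the high R:FR array of 16 °C, with all 6 pairs lower on the former. It was 0.64 on the low R:FR and 0.73 on the high R:FR array of 22 °C, again with all 6 pairs lower on the former. These 6 pairs cover only actin, GAPDH and ubiquitin, each more than once, so they are not 6 independent transcripts. Some gaps were small, such as 0.143 against 0.151 for a GAPDH pair at 22 °C. With a pseudocount in place of the floor the counts were 124 higher and 256 lower, and at 3-fold 74 and 109.

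**Figure D1:**
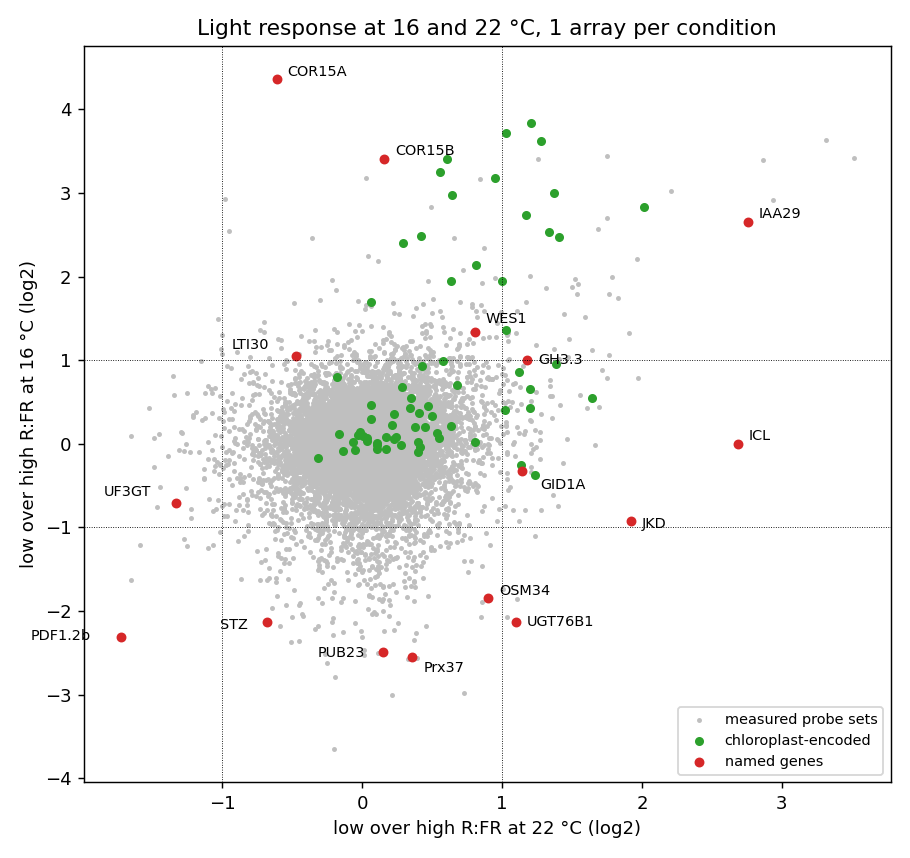
Each point is 1 of the measured probe sets, with the log2 change of low over high R:FR at 22 °C on the x axis and at 16 °C on the y axis, each from 1 array per condition, and dotted lines mark 2-fold. Green points are chloroplast-encoded and red points named genes; COR15A lies at 4.36 for 16 °C and -0.61 for 22 °C, and IAA29 at 2.66 and 2.76.

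The same light comparison at 22 °C gave fewer transcripts past 2-fold. IAA29 was again among them, with signals of 19.9 in high and 135 in low R:FR (log2 2.76, local SD 0.28, or 1.83 with a floor at the 50th percentile). ICL, the isocitrate lyase gene of the glyoxylate cycle, went from 20.5 to 132 (log2 2.68, local SD 0.47, or 1.80 with that floor). JKD, a zinc finger gene, was at least 3.78-fold higher, or 1.45-fold with a floor at the 50th percentile. GH3.3 was at log2 1.18 and WES1 at 0.80, so that the auxin list had 2 of 3 genes past 2-fold and a median of 1.18 at percentile 99.98. The 4 cell wall genes had a median of 0.52 at percentile 99.9, with XTH19 at 0.97, XTH33 at 0.59, EXPA8 at 0.45 and EXPA4 at -0.01. GID1A, a gibberellin receptor gene, was at 1.15, and its relative GID1B at 0.56.

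Flavonoid genes were lower at 22 °C as well, with 2 of 3 past 2-fold and a median of -1.25 that no random list reached (percentile 0). With a floor at the 50th percentile the median was -0.88, and AT4G14090 did not pass 2-fold. UF3GT had signals of 96.9 and 38.6, AT4G14090 of 63.9 and 26.8, and DFR of 209 and 114 (log2 -0.88). The lowest named change was that of PDF1.2b (767 and 232, log2 -1.73), followed by RR16, a response regulator gene, at least 2.81-fold lower, and PDF1.2 (164 and 59.2, log2 -1.47). CHR18 (log2 -1.12) and OSB1 (log2 -1.05) also passed 2-fold, whereas ATPC2 (log2 -0.99), LEP (-0.99), ATZW10 (-0.96) and ASF1B (-0.94) came next without passing it. RR16, CHR18 and OSB1 did not pass 2-fold with a floor at the 50th percentile.

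None of the 6 genes of the cold-regulated list passed 2-fold at 22 °C. Their median was 0.14 at percentile 78.8, with COR15A at -0.61, COR15B at 0.16 and LTI30 at -0.47. The light-harvesting genes had a median of -0.12 at percentile 41.5 and the reference genes of 0.10 at percentile 76.3. Of the 68 chloroplast-encoded probe sets 18 were at least 2-fold higher and 0 lower at 22 °C, 50 lay within 2-fold, and the median was 0.42. Those among the highest named genes were psbB (132 and 534), atpF (log2 1.64), accD (1.41), ndhK (1.39), psbT (1.37), psaC (1.34) and ndhG (1.28).

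In total 138 probe sets were at least 2-fold higher and 68 lower at 22 °C, so that 67% of those past 2-fold were higher. With arrays scaled to the same median that share was 53.6% (104 higher and 90 lower). At 3-fold the counts were 27 and 4.

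**Figure D2:**
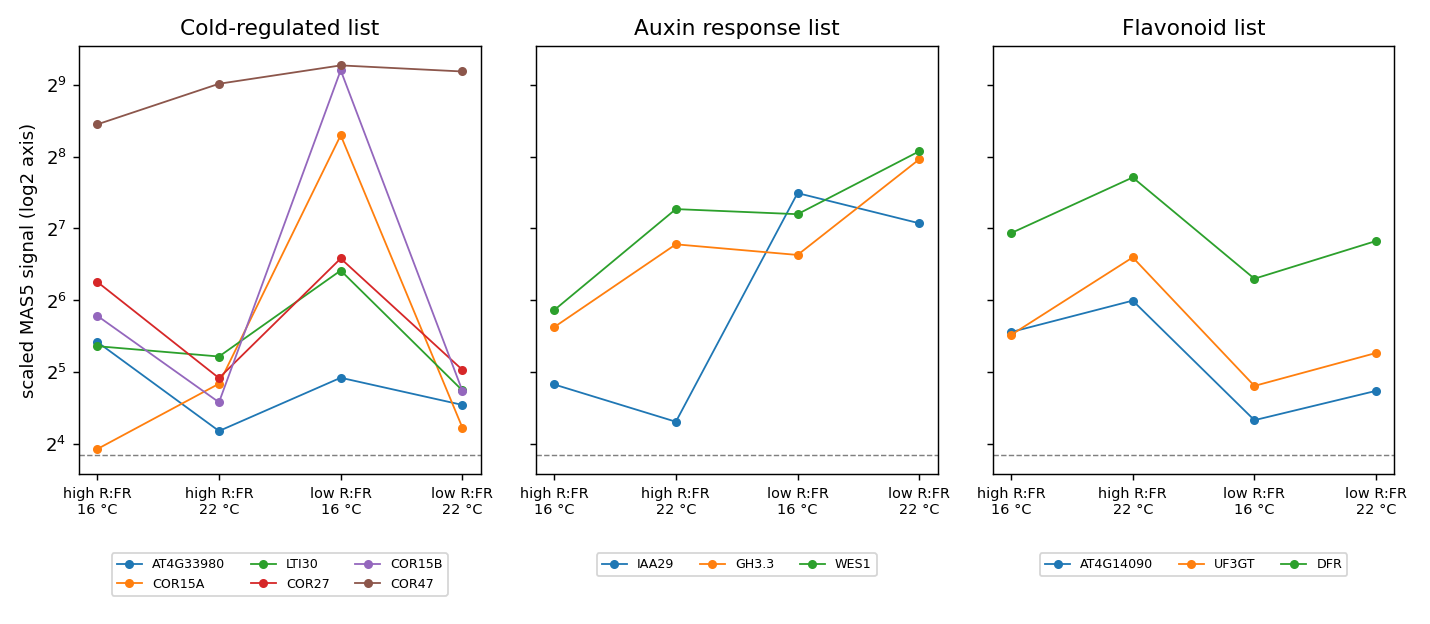
Scaled signals, on a log2 axis, of the measured genes of the cold-regulated, auxin response and flavonoid lists on the 4 arrays, 1 per condition; each coloured line joins the values of 1 gene and the dashed line is the floor of 14.5. COR15B stands at 588 in low R:FR at 16 °C and between 24 and 55.2 on the other arrays.

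The stated aim of the series was the dependence of the light response on temperature, given here as the log2 response at 16 °C minus that at 22 °C. COR15A had a difference of 4.97 (local SD 0.57), on 3 signals of at most 28.7, and COR15B of 3.25 (local SD 0.46). With a floor at the 50th percentile these were 3.05 and 3.41. The cold-regulated list had 3 genes past a difference of 1, LTI30 being the other at 1.52, and a median of 1.09 at percentile 100. Next came the chloroplast-encoded rps14 (2.80), ndhE (2.70, or 1.58 with a floor at the 50th percentile), petN (2.69), ycf3 (2.63), ndhG (2.34) and rpoB (2.34), with dim signals on the high R:FR array of 16 °C as given above. Over all 68 chloroplast-encoded probe sets the median difference was 0.07 at percentile 48.1, with 16 of at least 1 and 3 of at most -1. On the lower side were Prx37 (-2.91, or -1.66 with a floor at the 50th percentile), PUB23 (-2.64, or -1.71 with that floor) and MSRB9 (-2.25 with either floor). For 4 others 1 signal lay below the floor, which leaves a bound: the difference was at most -3.23 for UGT76B1, -2.84 for JKD, -2.75 for OSM34 and -2.09 for CW14. With a floor at the 50th percentile these 4 differences were -1.80, -0.54, -1.37 and -0.71, so that JKD and CW14 did not pass 1. For 6 of these 7 the lowest signal was that of the low R:FR array of 16 °C. ICL was below the floor on both 16 °C arrays, with signals of 3.2 and 3.5, so no difference is given for it. The gibberellin receptor genes GID1A and GID1B were at -1.47 and -1.09.

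Of the auxin response genes, IAA29 was at -0.10, GH3.3 at -0.18 and WES1 at 0.53, with a list median of -0.10 at percentile 36. That median turned to 0.42 with a floor at the 50th percentile and to 0.06 with a pseudocount. Cell wall genes had a median of 0.19 at percentile 82, flavonoid genes of 0.25 at percentile 81.7, light-harvesting genes of -0.11 at percentile 15.4 and reference genes of -0.45 at percentile 4.05. The difference was at least 1 for 315 probe sets and at most -1 for 568. It adds the error of 4 arrays. The spiked transcripts, which show only the part from hybridization onwards, had an SD of 0.36 and a largest size of 1.14. With a pseudocount the counts were 135 and 341.

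Across the measured probe sets, which are not independent replicates, the light responses of the 2 temperatures had a Pearson's r of 0.17 and a Spearman's rho of 0.10. These responses share no array. There were 49 probe sets at least 2-fold higher at both temperatures, where independent lists of these sizes would share 2.54, and 8 lower at both, against 1.97. Another 8 passed 2-fold in opposite directions.

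The temperatures were compared within each light condition. All plants were harvested at an age of 5 days. Any difference in growth stage between the temperatures at that age was not measured and cannot be told apart from temperature. This also holds for the difference of the light responses. In high R:FR, the lowest named changes at 16 °C were those of PDF1.2b and JRG21. PDF1.2b had signals of 71.8 at 16 and 767 at 22 °C (10.7-fold lower), JRG21, a jasmonate-induced oxygenase gene, of 45.4 and 416 (9.17-fold lower), PDF1.2 of 24.4 and 164, PUB19 of 22.6 and 147, OSM34 of 52.2 and 306, and ATPMEPCRD was at least 5.11-fold lower. Higher at 16 °C were the cold-regulated COR27 (76.5 and 30.3, log2 1.34), AT4G33980 (log2 1.24) and COR15B (55.2 and 24), the sucrose phosphate synthase gene ATSPS4F (346 and 167), the sugar transporter gene SWEET13 (log2 1.04) and GRXC1 (1.03), with F2KP next at 0.93. COR15B, AT4G33980, SWEET13, GRXC1 and ATPMEPCRD did not pass 2-fold with a floor at the 50th percentile. Without the demand for a symbol, 0 of the 6 highest and 2 of the 6 lowest changes had one. Of the cold-regulated list 3 of 6 passed 2-fold, of which only COR27 did with a floor at the 50th percentile. The list median was 0.67 at percentile 99.99. It was 0.15 with a floor at the 50th percentile and 0.46 with a pseudocount. COR15A was at -0.91 and COR47 at -0.56. The auxin list had a median of -1.15 at percentile 0.05, from WES1 at -1.40, GH3.3 at -1.15 and IAA29 at 0.52. Flavonoid genes had a median of -0.77 at percentile 0.665, with UF3GT past 2-fold, and cell wall genes of -0.47 at percentile 2.21. The light-harvesting median was 0.01, and turned to -0.03 with quantile normalization, and that of the reference genes was 0.13. Chloroplast-encoded probe sets had a median of -0.47, with 16 lower and 0 higher, and mitochondrion-encoded ones of -1.23, or -0.32 with a floor at the 50th percentile.

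In low R:FR, COR15B was 21.9-fold higher at 16 than at 22 °C, with signals of 588 and 26.8, and COR15A 16.7-fold, with 314 and 18.8. With a floor at the 50th percentile these were 15.5-fold and 8.31-fold. LTI30 followed at 3.17-fold, beside the chloroplast-encoded rps14 (log2 2.27), petD (1.76) and rpoB (1.66), and COR27 was at 1.55. This made 4 of the 6 genes of the cold-regulated list, with a median of 1.61 at percentile 100, or 1.26 with a floor at the 50th percentile. Over all 68 chloroplast-encoded probe sets 8 were at least 2-fold higher and 8 lower at 16 °C. Their median was -0.21 at percentile 0, or -0.03 with arrays scaled to the same median. The lowest named genes were OSM34, at least 39.4-fold lower at 16 °C, JRG21, at least 35.4-fold, PDF1.2b, at least 16-fold, ICL, at least 9.09-fold, PUB23 (log2 -2.95, or -2.02 with a floor at the 50th percentile) and the glucosidase gene BGLU46 (-2.94, or -1.67 with that floor). The 16 °C signal of BGLU46, 15.6, lay below the highest of the absent controls. STZ was at -2.39. The auxin list had a median of -0.87 at percentile 1.54, the flavonoid list of -0.46 at percentile 11.9 (-0.03 with a floor at the 50th percentile), the cell wall list of -0.20 at percentile 24.4, the light-harvesting list of -0.35 at percentile 4.62 and the reference list of -0.31 at percentile 15.4. With arrays scaled to the same median these were -0.70 for the auxin, -0.28 for the flavonoid, -0.02 for the cell wall, -0.17 for the light-harvesting and -0.13 for the reference list. PYK10, a glucosidase gene strongly expressed in roots and the only measured root marker, had signals of 1083 at 16 and 2835 at 22 °C (log2 -1.39).

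In high R:FR 151 probe sets were at least 2-fold higher and 432 lower at 16 °C, and in low R:FR 221 and 902. The share higher was 25.9% and 19.7%. With arrays scaled to the same median it was 41.6% and 40.2%, since that scaling moved the median log2 of all measured probe sets by 0.12 and 0.18, and with quantile normalization 35.8% and 30.2%. The temperature responses of the 2 light conditions, which share no array, had a Pearson's r of 0.50 and a Spearman's rho of 0.48 across probe sets. There were 199 probe sets lower at 16 °C in both, against 28.6 for independent lists, and 41 higher in both, against 2.45.

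Over all 4 arrays, limma with a term for light and a term for temperature asked for transcripts that changed alike in both comparisons. For light it called 7 probe sets higher and 0 lower at an adjusted p under 0.05, with 536 higher and 364 lower at an unadjusted p under that value. IAA29 rose by log2 2.71 (SE 0.19, adjusted p = 0.0164, limma), as did AT5G02540 (log2 2.09, SE 0.17, adjusted p = 0.0285). The other 5 had no gene name here, and the largest effect among them was log2 3.48, with 1 of its signals, 2.4, set to the floor. The next, of log2 3.47, had both high R:FR signals, 7.1 and 13.9, set to the floor. That removed its temperature difference in high R:FR, which enters the error of the fit. Another, of log2 3.13, had a signal of 13.9 set to the floor. The next smallest adjusted p-values belonged to psbB (log2 2.43, adjusted p = 0.0532), PDF1.2b (log2 -2.02, adjusted p = 0.0714) and AT5G62360 (log2 -1.64, adjusted p = 0.0786), which did not pass. Of the auxin list 1 of 3 genes was called over all probe sets and 3 when adjusted over the list alone. For the flavonoid list these counts were 0 and 3, all lower, for the cell wall list 0 and 2 (XTH19 and EXPA8, higher), for the light-harvesting list 0 and 1 (LHCB4.2, lower), and for the cold-regulated and reference lists 0 and 0. The adjustment over a list alone does not cover the number of lists. Adjusted over all 32 measured listed genes together, XTH19 was not called. The test rests on 1 residual degree of freedom, so a response confined to 1 temperature, like that of COR15A (log2 1.87, SE 1.03, adjusted p = 0.79), counts as error in it. Without the temperature term, without the variance trend or without the filter it called 0 probe sets for light.

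For temperature the same fit called 48 probe sets higher and 143 lower at 16 °C. The smallest adjusted p was that of PDF1.2b, which fell by 3.71 on the log2 scale (SE 0.20, adjusted p = 0.00991, limma), and AT4G23680 fell by 2.33 (SE 0.15, adjusted p = 0.00991). AT3G05730 rose by 1.43 (SE 0.12, adjusted p = 0.0185), and the other 7 of the 10 smallest had no gene name here. Further named genes past the threshold were JRG21 (log2 -4.17, adjusted p = 0.0318), PDF1.2 (log2 -2.39, adjusted p = 0.0356), OSM34 (log2 -3.92, adjusted p = 0.0457), GH3.3 (log2 -1.24, adjusted p = 0.0446), COR27 (log2 1.44, adjusted p = 0.0446), F2KP (log2 0.93, adjusted p = 0.0446), ATPMEPCRD (log2 -2.10, adjusted p = 0.0446), ndhK (log2 -1.28, adjusted p = 0.0446) and ATSPS4F (log2 0.99, adjusted p = 0.0457). The effects of PDF1.2b, JRG21, PDF1.2, OSM34 and ATPMEPCRD rest on 16 °C signals of which at least 1 lay below the floor. In the cold-regulated list 1 of 6 genes was called over all probe sets, COR27, and 2 when adjusted over the list alone, with COR15B, both higher at 16 °C. In the auxin list these counts were 1 (GH3.3) and 3, of which IAA29 was higher and the others lower at 16 °C. For the flavonoid list they were 0 and 2, for the cell wall list 0 and 1 and for the light-harvesting list 0 and 1, all lower, and for the reference list 0 and 0. Adjusted over all 32 measured listed genes together, IAA29 and UF3GT were not called for temperature. With arrays scaled to the same median the counts were 159 higher and 143 lower, and without the variance trend or the filter 0 were called, with 943 higher and 1695 lower at an unadjusted p under 0.05 without the trend.

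Single genes stood for several other lists. HAT2, which with IAA29 made up the measured shade list, was at log2 0.55 at 16 and 0.59 at 22 °C for light. GI of the clock list was at 0.21 and 0.49, PORB of the chlorophyll list at -0.12 and -0.06, SAG101 of the salicylate list at -0.58 and -0.51, AKINBETA1 of the starvation list at 0.01 and 0.10, and PDF1.2 of the jasmonate list at -1.47 at 22 °C and at most -0.75 at 16 °C, where its low R:FR signal lay below the floor. The sign for AKINBETA1 at 16 °C turned with quantile normalization.

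**Figure D3:**
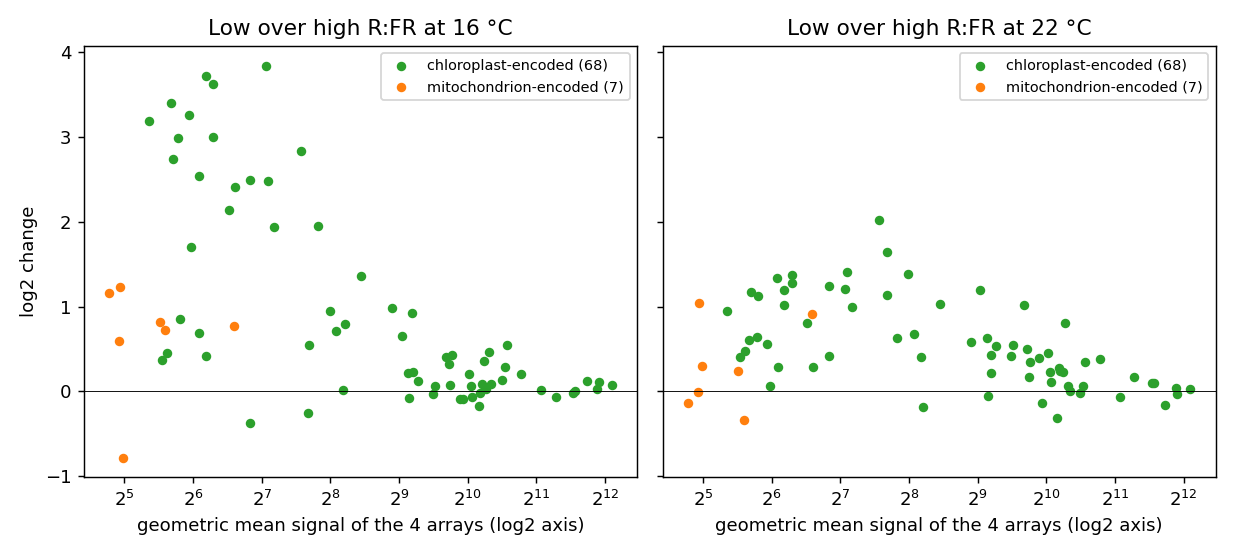
Log2 change of low over high R:FR at 16 °C (left) and 22 °C (right) against the geometric mean signal of the 4 arrays on a log2 axis, for 68 chloroplast-encoded (green) and 7 mitochondrion-encoded (orange) probe sets, 1 array per condition. The chloroplast-encoded probe sets with changes above 1 lie at the dimmer end in the left panel, where the Spearman's rho of change with mean signal was -0.68. In the right panel that rho was -0.66.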

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

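Of 71 named genes and measured list members, 7 had light responses of opposite sign at the 2 temperatures, each of at least log2 0.5. The differences were not tested, since there was 1 array per condition, and that minimum and all tests in this part were chosen after the values were seen. The response at 16 °C minus that at 22 °C was 4.97 for COR15A, 1.48 for ATZW10, -1.35 for GRXC1 and -1.09 for GID1B. It was at most -3.23 for UGT76B1, -2.84 for JKD and -2.75 for OSM34, bounds because the signals of UGT76B1 and OSM34 in low R:FR at 16 °C, 7.5 and 12.1, and that of JKD in high R:FR at 22 °C, 8.7, lay below the floor. With a floor at the 50th percentile only UGT76B1, at -1.80, still had responses of opposite sign of at least 0.5. COR15A was then at 3.05, JKD at -0.54, OSM34 at -1.37, ATZW10 at 0.47, GRXC1 at -1.12 and GID1B at -0.53. With median scaling or quantile normalization GRXC1 was at 0.46 at 22 °C. With a pseudocount COR15A (-0.38 at 22 °C), ATZW10 (0.36 at 16 °C), GRXC1 (0.37 at 22 °C) and GID1B (0.43 at 22 °C) were also under 0.5 in size.

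COR15A and COR15B were high on the low R:FR array of 16 °C alone. A wrong light label on that array is argued against by the 119 probe sets, organelle-encoded ones left out, that were higher in low R:FR at 22 °C: their median log2 light response at 16 °C was 0.50, above the 95% range of random lists (-0.08 to 0.11). Plants grown at 22 °C are argued against by the 432 probe sets lower at 16 °C in high R:FR, whose median was -0.92 in low R:FR, below the range of random lists (-0.14 to -0.03). Whether the paralogs count as 1 or as 2 responses cannot be told apart, because their temperature responses in high R:FR differed by 2.11 on the log2 scale but rest on signals of 15.3 to 55.2, partly below the filter. An effect of low R:FR on the cold-regulated genes at 16 °C, the condition the design names, stays open beside variation between single plant samples, which no repeat measured.

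Chloroplast-encoded transcripts were lowest on the high R:FR array of 16 °C. Less labelled organelle RNA of every kind in that sample is a candidate explanation: the 7 mitochondrion-encoded probe sets had a median log2 of -1.23 for 16 over 22 °C in high R:FR, below every random list. That median was -0.32 with a floor at the 50th percentile. Comparisons without that array also differed, which a deficit in that sample alone would not explain. At 22 °C the chloroplast-encoded median was 0.42 in low over high R:FR, with 18 of 68 probe sets at least 2-fold higher and 0 lower. In low R:FR their median of 16 over 22 °C was -0.21, or -0.03 with arrays scaled to the same median. That of the mitochondrion-encoded probe sets was -0.58, or -0.17 with a floor at the 50th percentile. Whether a single factor for all chloroplast RNA is the whole explanation was not decided. The 23 dim probe sets (mean signals 41 to 190) had a light response at 16 °C 2.16 higher (SE 0.35) than the 23 of middle signal (204 to 978), whose median was 0.33. The mean signals that set these groups include the compared arrays, so a strong fall on a compared array itself makes a probe set dimmer. The SE also treats probe sets of the same arrays as independent. A change of particular chloroplast transcripts with light or temperature stays open and was not tested.

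On the low R:FR array of 16 °C, 258 probe sets lay at least 2-fold below all other arrays. Scaling is argued against, since 241 did so after quantile normalization, when the next array had 55. Random noise of the array stays open, although only 30 probe sets lay at least 2-fold above all others. The filter on mean signal tends to remove probe sets that are near the floor on all other arrays. The counts above and below therefore cannot decide this. Less root or lower stem tissue in that harvest cannot be told apart from a response of the plants. PYK10 was at log2 -0.90, but it was the only measured root marker. Its signals were 1083 to 2913 over the arrays, while EXPA7 and EXPA18 lay near or below the floor on every array. PYK10 therefore need not report root tissue here and cannot decide this. The stated harvest of cotyledons with a little hypocotyl would leave roots out. The 3'/5' signal ratios of all 6 control pairs were lower on that array than on the high R:FR array of 16 °C (mean log2 0.54 and 0.82), so that it had less excess of 3' signal. All 6 pairs were also lower in low than in high R:FR at 22 °C, where 17 probe sets lay at least 2-fold below all others on the low R:FR array. These pairs cover only actin, GAPDH and ubiquitin, each more than once. A difference in RNA or label quality stays open. A response to the combination of light and temperature stays open and was not tested.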

How the results depend on the processing

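The setting without organelle-encoded probe sets was chosen after the data were seen, as were 3 settings for the correlation of the light responses (values as deposited, median scaling and a pseudocount); all others were planned. Values as deposited and that setting kept every count within 1.5 times. The cause of other moves was not tested, except that stricter or looser filters and fold rules count fewer or more probe sets by construction. The fit with both terms compares the light conditions within each temperature, with 1 residual degree of freedom, and the fit without the other factor drops that pairing. Leaving out an array leaves no residual degree of freedom. A signal below the floor gives a fold only as a bound.

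Counts are given as higher and lower, in the order light at 16 °C, light at 22 °C, difference, temperature in high R:FR and temperature in low R:FR. With a floor at the 50th percentile they were 119 and 205, 63 and 18, 124 and 284, 70 and 224, and 144 and 536. With a pseudocount in place of the floor they were 124 and 256, 63 and 15, 135 and 341, 59 and 226, and 116 higher. With the filter at the 60th percentile they were 102 and 208, 51 and 15, 89 and 248, 59 and 193, and 125 and 475. At 3-fold they were 74 and 109, 27 and 4, 69 and 162, 24 and 78, and 34 and 293. Without a filter the difference was at least 1 for 501. Scaling to the same median gave 430 higher at 16 °C in low R:FR.

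The limma light effect had 0 calls without the trend, without the temperature term, with a floor at the 50th percentile and without a filter, 3 higher with a floor at the 10th percentile, and 2, 1 and 1 lower with median scaling, quantile normalization and a pseudocount. All 7 main calls were among those of the 3 last settings. The temperature effect had 0 calls without the trend, with a floor at the 50th percentile and without a filter, 7 higher and 29 lower without the light term, 6 and 18 with a floor at the 10th percentile, 9 and 36 with a pseudocount, and 159 higher with median scaling. No value of a gene or list that was called changed sign: 511 of 603 alternative values of named genes, 489 of 545 of list medians and 144 of 215 of genes in the fit kept within their spread or side of the threshold. The auxin median of the difference, which was not called, turned from -0.10 to 0.42 with a floor at the 50th percentile and to 0.06 with a pseudocount. With that floor the flavonoid median fell in size from 0.71 to 0.32 for light at 16 °C, and the cell wall median from 0.55 to 0.34. The correlation of the light responses, 0.17, ranged from 0.13 without a filter to 0.23 with the filter at the 60th percentile over 9 alternatives.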

Other observations

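The gene families here were chosen after their values were seen, and no difference between temperatures was tested for them. Among 6 measured WRKY transcription factors, which regulate defence and senescence genes, the median log2 was -0.60 at 16 °C (percentile 0.08 of random lists) and 0.08 at 22 °C (percentile 68.4), and of the difference -0.70 (percentile 0.09), with 2 past 2-fold at 16 °C, WRKY6 (signals 60.2 and 20.2) and WRKY53 (90.4 and 35.8). With a floor at the 50th percentile WRKY6 did not pass 2-fold, whereas WRKY53 did. The 7 peroxidase genes had medians of -0.58 (percentile 0.04) and -0.05 (percentile 43), and of the difference -0.17 (percentile 8.52). The first of these is the value of AT2G41480, which rests on a signal of 6.2, below the floor. Over the alternatives it ranged from -1.11 to -0.16, and that of the difference from -1.12 to -0.11. At 16 °C 3 passed 2-fold, with AT5G64120 going from 562 to 91.5, Prx37 at -2.55 and PRX52 at -1.11. Of these, PRX52 did not pass with a floor at the 50th percentile. Of 6 plant U-box ubiquitin ligase genes, PUB22 (68 and 21.7) and PUB23 were at least 2-fold lower at 16 °C. PUB19 (22.6 and 80.9) was at least 2-fold higher. PUB22 did not pass 2-fold with a floor at the 50th percentile, whereas PUB23 and PUB19 did. The medians of the 6 genes were -0.42 (percentile 0.61) and 0.18 (percentile 86), and of the difference -0.63 (percentile 0.22). The 22 genes with a UGT symbol, of UDP-glycosyltransferases, had medians of -0.28 (percentile 0.15) and 0.13 (percentile 92.5), and of the difference -0.41 (percentile 0.02), with 3 past 2-fold lower at 16 °C, UGT76B1, UGT72E1 (106 and 49.3) and UGT87A2 (143 and 71). UF3GT and AT4G14090 (UGT75C1), listed above as flavonoid genes, encode glycosyltransferases too, with differences of 0.62 and 0.03. With them the 24 genes had medians of -0.30, 0.11 and -0.40. Over the alternatives the medians of the 22 ranged from -0.30 to -0.16, from 0.02 to 0.13 and from -0.41 to -0.32. Those of the U-box genes ranged from -0.42 to -0.27, from 0.07 to 0.18 and from -0.63 to -0.43, and those of the WRKY genes from -0.60 to -0.49, from 0.03 to 0.08 and from -0.70 to -0.57. The low signals of the genes that were lower in low R:FR at 16 °C are those of the array on which 258 probe sets lay at least 2-fold below all others.

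Expansins are proteins that loosen cell walls. The group here also holds the expansin-like genes EXLB1 and EXLA2, and it shares EXPA4 and EXPA8 with the cell wall list. Of its 11 measured genes, 10 were above 0 in low R:FR at 16 °C, with a median of 0.45 (percentile 99.96) against -0.01 at 22 °C (percentile 44.2), the value of EXPA4. The median difference was 0.54 (percentile 99.92). Over the alternatives the medians ranged from 0.30 to 0.46, from -0.06 to 0.01 and from 0.30 to 0.61. EXLB1 passed 2-fold at 16 °C (29.2 and 60.4), and EXLA2 at 22 °C (20.7 and 45.2). Neither passed with a floor at the 50th percentile. The 12 TBL genes, of cell wall acetylation, had medians of 0.23 (percentile 97.1) and 0.02 (percentile 47.5), and of the difference 0.18 (percentile 91.2). That at 16 °C ranged from 0.15 to 0.24 over the alternatives, and that at 22 °C turned to -0.04 with scaling to the same median and to -0.01 with quantile normalization.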
